A study of Mus musculus with 30 samples.

How the data were processed

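Gene expression was measured in mouse cells derived from Ainv18 embryonic stem cells, a line engineered so that doxycycline (dox) turns on an activated form of the receptor Notch4. Per the labels, cells positive for a Brachyury-GFP reporter and for Flk-1, the receptor encoded by Kdr, were sorted from embryoid bodies and reaggregated for 24 h with or without dox. They were then washed and cultured without dox, and total RNA was taken at 4, 12, 24, 48 or 96 h. The cells taken at 4, 12 and 24 h had therefore been in dox until harvest, and those taken at 48 and 96 h had been washed. The 30 samples fell into 10 groups of 3, marked A, B and C within each group. The labels do not say what the letters mark, so the p-values measure the spread between these samples. No arm with dox but without the transgene was included, so an effect of dox itself cannot be separated from that of Notch4.

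Per the labels and the file headers, RNA was labelled with Alexa-647 by the CodeLink protocol and each sample was read on its own slide with CodeLink Expression Analysis 4.1. The scanner files hold the mean intensity of each spot and the median intensity of its local background. The deposited value table also holds an intensity, not on a log scale. In it the authors gave the spot mean minus the background median, divided by a constant for each array near that array's median, and left contaminated or irregular spots blank. This was checked: the table and the scanner files differed in 0 values by more than 0.0001. RNA input, scan dates and slide batches are not given in the sources used here.

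Intensities were recomputed from spot mean and background median with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8). The normexp background correction with an offset of 50 was followed by a log2 transform and quantile normalization across the 30 arrays. A probe was kept when the scanner placed it above background on all 3 arrays of at least 1 group. The scanner's low mark was checked to equal a spot mean at or under the background median plus 1.5 background SD. Of 36227 spots, 21615 carried 1 gene, 681 several and 13931 none in the annotation used; 21487 symbols were updated through the gene identifier. Control spots could not be told from probes without a gene name. The tests covered 25733 probes and 14403 genes, each gene represented by its probe with the highest mean intensity.

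A mean was fitted for each of the 10 groups with lmFit, and eBayes shared 1 estimate of spread among them (20 residual and 3.96 prior degrees of freedom). The tests were the 5 differences between dox and no dox cells at the same time, moderated F-tests for any dox effect and for a dox effect that differed between times, and the difference between 96 and 4 h in the no dox cells. All were two-sided. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all probes. Values are given as log2 fold change ± SE, with 3 arrays per group. The SE uses the spread shared by all 10 groups, so it can differ from that of the arrays compared. For Tnni3 at 96 h, with an SE of 0.47, the SD was 0.30 with dox and 1.76 without. For Tnnt2 at 24 h, with an SE of 0.45, it was 0.07 with dox and 0.19 without. For a dox effect, rose and fell mean higher or lower than in no dox cells of the same time, not a change over time. Where the lower group lay at background on all its arrays, or the higher group was saturated, the fold is given as a lower bound ("at least"). Where only some of a group's arrays lay above background, the fitted value is given and their number is stated.

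The 34 gene lists and the 20 marker genes were fixed before the data were examined. The labels name the Notch, Wnt and BMP/TGF-beta pathways as the study's focus, and lists for these were included for that reason. Lists were tested with camera at a preset correlation of 0.01 over 14204 genes, and again with the correlation estimated for each list. Counts over a list are given at the threshold adjusted over all probes and, where stated, adjusted over the list alone. Genes were named by a rule also fixed before the data were examined: the 6 largest rises and 6 largest falls at each time among called genes whose 3 dox arrays all lay on the same side of the 3 no dox arrays, up to 3 members of each list with the smallest adjusted p, and the marker genes. Chance places 3 arrays apart from 3 in 10% of genes. Genes named outside this rule are said to be so. The marker Hbb-bh1 had no probe here.

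The steps were tested on simulated data with 25369 probes, 10 data sets for each of 2 settings. With equal spread in all groups, 4.28% to 5.51% of the calls at a single time were false, and changes of 2 log2 units were recovered in 96.7% to 98.6% of probes. With each group's own spread, the false share was 14.4% at 4 h, 11.7% at 12 h, 0.755% at 24 h, 1.84% at 48 h and 13.5% at 96 h, so the shared spread is optimistic at 4, 12 and 96 h. Changes of 0.5 log2 units were recovered in 28.8% to 34.8% of probes at a single time. In the simulated list test the 1 planted list was called and 0 of the others were. The simulated probes varied independently of each other, so this does not test the list calls where genes of a list vary together. No array that stood apart was simulated either. With each group's own spread the simulated sets averaged 146 to 172 calls at a time, against 0 at 4 h and 7168 at 96 h in the data. The false share depends on how many probes change, so these shares do not give that of the data. The number of arrays limits the precision.

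The alternatives covered background correction, scaling, the filter on dim probes, spot quality marks, the deposited value table, array weights, the variance prior, the arrays in the fit, the letters as a block, the probe per gene and the correlation in the list tests and each array left out. Figures were drawn with matplotlib 3.10.9.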

Results

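The study asked which genes follow when activated Notch4 is switched on in Flk-1 positive mesoderm cells, and compared dox with no dox cells at 5 times. Each of the 30 arrays held 36227 spots, of which 62.7% to 68.7% lay above background, and the median spot was 2.28 to 2.84 times as bright as its background. Across probes, which are not independent replicates, Pearson r between arrays of a group lay between 0.939 and 0.995, lowest for arrays A and B of the 4 h no dox group. A principal component with 40.2% of the variance ran from 4 h to 96 h, and the next, with 14.6%, parted dox from no dox cells at 24, 48 and 96 h, and by less at 12 h. The fourth component (6.01%) placed the 12 h dox arrays A and B at -37.2 and -30.3, near the 4 h no dox array A at -45.8. The 12 h dox array C lay at 24.2 on it, among the 12 h no dox arrays at 19.3 to 30.4.

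The Notch4 probe itself did not pass the test at any time in the main fit, the one described above. On arrays A, B and C its log2 intensity was 7.76, 6.55 and 7.13 without dox and 7.34, 6.44 and 7.26 with dox at 4 h, and 6.66, 6.39 and 6.37 without and 7.0, 7.50 and 7.28 with dox at 12 h. At 24 h it was 6.79, 6.97 and 6.82 without and 7.20, 7.40 and 7.37 with dox, and at 48 h 6.38, 6.83 and 6.96 without and 7.53, 7.24 and 7.17 with dox. At 96 h it was 7.05, 6.61 and 7.01 without and 7.04, 6.88 and 6.69 with dox. The probe was above background on 2 of 3 arrays of either group at 4 h. Without dox it was so on 1 of 3 at 12 h and 2 of 3 at 48 h, and in the other groups on all arrays. The log2 fold changes, each ± 0.24 (SE), were -0.13 at 4 h (adjusted p = 0.953), 0.78 at 12 h (0.0538), 0.46 at 24 h (0.419), 0.59 at 48 h (0.0934) and -0.02 at 96 h (0.964). All 3 dox arrays lay above all 3 no dox arrays at 12, 24 and 48 h, and the 12 h call depends on the processing. There the probe passed in 7 of 18 alternatives (adjusted p from 0.00227 to 0.301): with the letters as a block (0.043), array weights (0.00227), median scaling (0.0476), cyclic loess (0.0457), only probes with 1 gene symbol (0.0409), without the 4 h no dox arrays A and B and the 12 h dox array C (0.0141), or without that last array alone (0.0473). At 24 h it passed in 1 of 18, with only the arrays compared (0.0234; range 0.0234 to 0.711). At 48 h it passed in 2 of 18, with only the arrays compared (0.0444) and without the same 3 arrays (0.0357; range 0.0357 to 0.361).

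**Figure D1:**
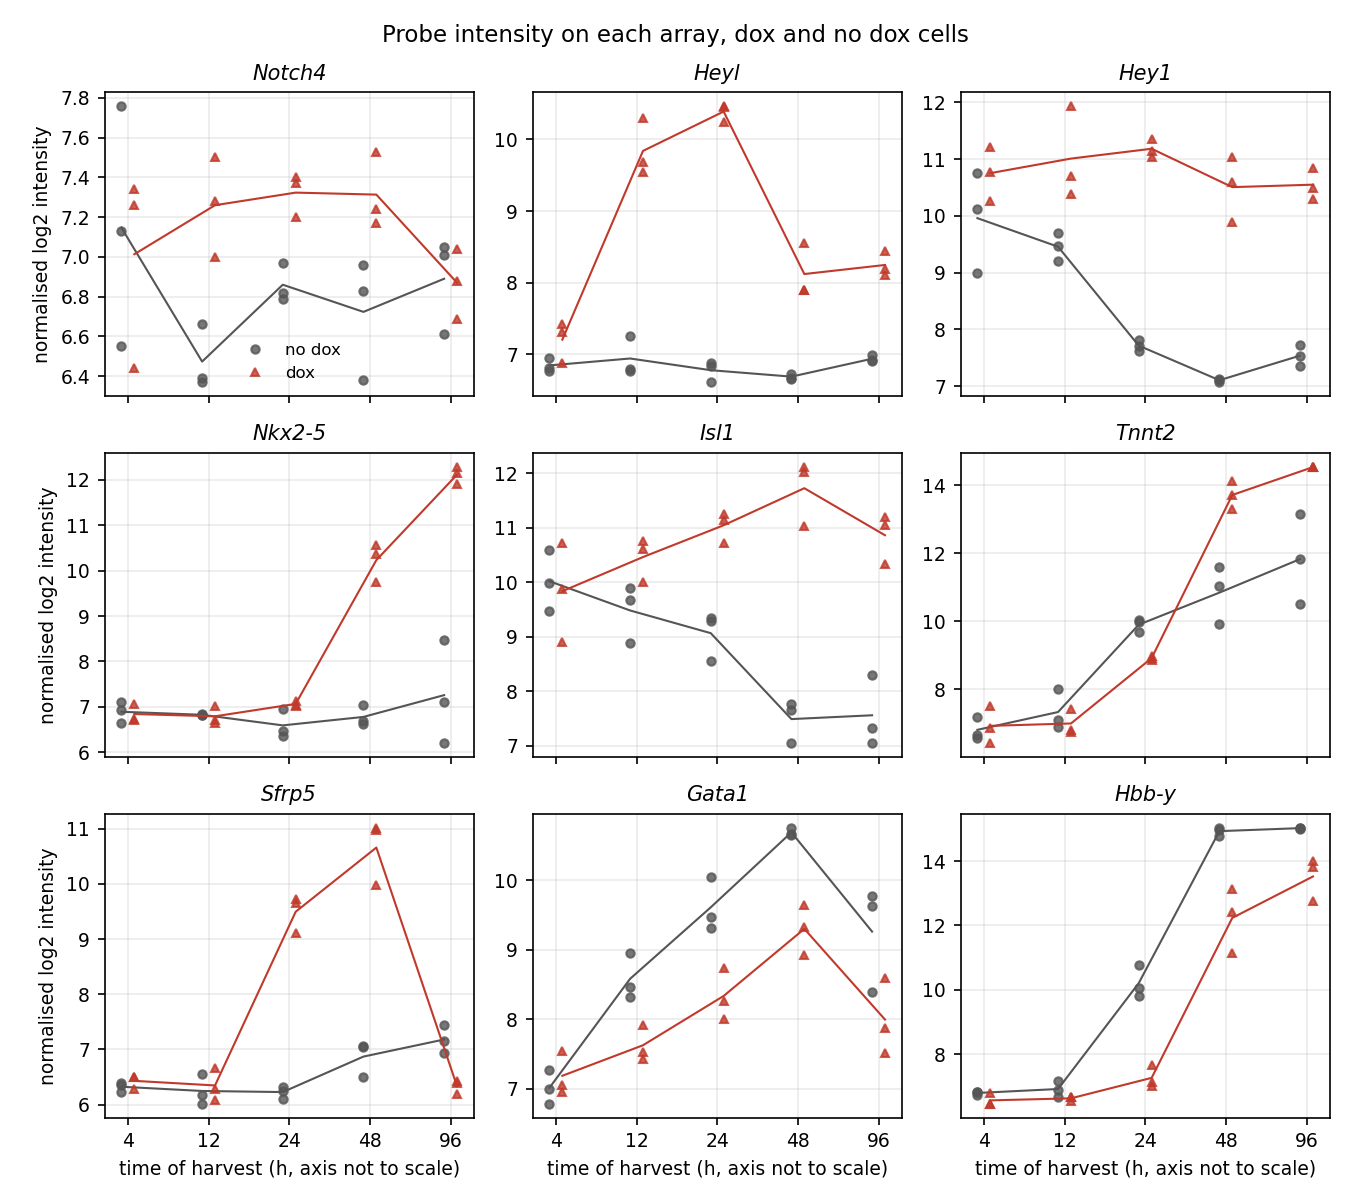
Normalised log2 intensity (vertical axis) of 9 genes against time of harvest in h (horizontal axis, not to scale), for dox (triangles) and no dox cells (circles). Each point is 1 array and each line joins the means of 3 arrays. Heyl and Hey1 stood higher with dox from 12 h, Nkx2-5 and Tnnt2 from 48 h, and Hbb-y stood lower from 24 h.

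At 4 h no single gene passed the test. Genes known to be switched on by Notch nevertheless stood higher with dox as a group, with a median over the 9 Notch target genes of 0.65 log2 units (0.34 with marked spots missing). By letter, 8 of the 9 were higher with dox on A (median 1.27), 3 on B (median -0.07) and 8 on C (median 0.51). Nrarp, a feedback inhibitor of Notch, stood at 1.25 ± 0.34 (adjusted p = 0.337) and the repressor Hes1, above background on 2 of 3 no dox arrays, at 0.65 ± 0.19 (adjusted p = 0.339). Adjusted over the list alone, 2 of the 9 rose. Camera called the list (adjusted p = 0.00222), but not with the estimated correlation (adjusted p = 0.775). The call was lost without the no dox array A (median 0.326, adjusted p = 0.0736) or the dox array A (median 0.393, adjusted p = 0.0999), or with only probes above background on all arrays (0.154), and without the dox array C the median was 0.316 (adjusted p = 0.0282). The 19 mitotic (G2/M) genes were called as higher, with a median of 0.20 (0.337 without the no dox array C), 0 members past the threshold, and an adjusted p = 0.0352 that became 0.978 with an estimated correlation. That call was lost without the no dox array A (adjusted p = 0.383), the no dox array B (0.179), the dox array B (0.0541) or the dox array C (0.328). It was also lost in 8 of 14 settings. Without the 4 h no dox arrays A and B and the 12 h dox array C the median was 0.044 (adjusted p = 0.721), which sets the 3 dox arrays against the no dox array C alone, assumed to vary like the other groups. The median was 0.108 with array weights (adjusted p = 0.0814) and 0.131 with marked spots missing (0.268). The other 5 were no background correction (0.0536), the letters as a block (0.0555), the mean of all probes of a gene (0.0788), only probes above background on all arrays (0.13) and the deposited value table (0.178); with median scaling the median was 0.39 (adjusted p = 0.00565). None of the other markers passed; Hey1 stood at 0.79 ± 0.36 (adjusted p = 0.449) and Kdr at -0.17 ± 0.22 (adjusted p = 0.916).

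In limma 0 of 25733 probes passed at 4 h, against 2654 at an unadjusted p under 0.05. Leaving out 1 array gave 36 probes without the no dox array B, 2 without the no dox array C and 1 without the dox array C.

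At 12 h the Notch target genes stood higher with dox than without. Of 9 measured, 5 rose, 0 fell and 4 did not pass, and 6 rose when adjusted over the list alone. Heyl, a transcriptional repressor, rose by 2.90 ± 0.18 (adjusted p = 4.6e-10), Hes5 at least 5.02-fold (adjusted p = 8.46e-05), Dtx1 by 1.87 ± 0.27 (adjusted p = 0.000173) and Nrarp, named here after its value was seen, by 1.94 ± 0.34. Hey1 rose by 1.56 ± 0.36 (adjusted p = 0.0151), a call lost without the no dox array A (0.0536) or B (0.0557), whereas Hes1 stood at -0.05 ± 0.19 (adjusted p = 0.938). The list was called (camera adjusted p = 9.8e-08; 0.0471 with an estimated correlation). Its median of 1.56 was 0.926 with no filter on dim probes, 0.342 with the deposited value table and 0.296 with marked spots missing, and the call held in each. The 6 largest rises were Gpbar1, a bile acid receptor (at least 9.99-fold), Dmrta1 (3.32 ± 0.29), Krt79 (3.28 ± 0.35), the adhesion molecule Cdh1 (3.13 ± 0.36), the pancreatic carboxypeptidase Cpa1 (2.90 ± 0.25) and Heyl. The largest falls were Tdo2, an enzyme of tryptophan breakdown (-2.19 ± 0.46), Myc (-2.14 ± 0.30), Cldn11 (-1.98 ± 0.19), Csrp1 (-1.81 ± 0.28), Dusp9 (-1.71 ± 0.25) and Polg (-1.60 ± 0.19). The Tdo2 call was lost without the dox array B (adjusted p = 0.074), and with only the 12 h arrays those of Hey1 (0.152), Csrp1 (0.11) and Dusp9 (0.121) were. Without dox Dmrta1 was above background on 1 of 3 arrays and Dtx1 on 2, and with dox Hes1 on 2.

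Signalling genes and blood progenitor genes also differed at 12 h. Of 16 Wnt ligands 4 rose, 0 fell and 12 did not pass: Wnt3 (1.26 ± 0.17, adjusted p = 8.59e-05), Wnt4 (1.99 ± 0.46), Wnt2b (0.67 ± 0.16) and, named after its value was seen, Wnt2 (1.02 ± 0.28). The Wnt4 call was lost without the dox array A or B (adjusted p = 0.0939 and 0.0616). It was also lost without the no dox array B or C (0.0557 and 0.0569). A second, dimmer Wnt4 probe passed, at 1.69 ± 0.29 (adjusted p = 0.000974). The Wnt2b call was lost without the no dox array B (0.101), and without the dox array C Wnt2b stood at 0.417 (0.041). The Wnt2 call was lost without the no dox array A, B or C (0.0697, 0.103 and 0.127) or the dox array B or C (0.0924 and 0.104), and without the dox array C its value was 0.593. The list was called (camera adjusted p = 0.00466, and 0.0471 with an estimated correlation), but not without the dox array C (0.0966). Of 14 other settings 3 also ended this call, with a highest adjusted p of 0.224. Of 16 BMP and TGF-beta ligands 3 rose and 1 fell: Bmp6 rose by 2.20 ± 0.26, Bmp2 by 1.07 ± 0.18 and Bmp7, named after its value was seen, by 0.73 ± 0.21. The list was not called (adjusted p = 0.369). The Bmp7 call was lost without any 12 h array but the dox array C (adjusted p = 0.0846, 0.159 and 0.124 without the no dox array A, B or C, and 0.152 and 0.282 without the dox array A or B). Bmp4 was the gene that fell, by 0.70 on the log2 scale (SE 0.19), a call lost without the dox array A (adjusted p = 0.285) or B (0.213) or the no dox array B (0.174) or C (0.113). Of 17 haematopoietic progenitor genes 4 fell, 0 rose and 13 did not pass, with the stem cell factor receptor Kit at -1.16 ± 0.16, Gata2 at -1.05 ± 0.18, Lyl1 at -1.14 ± 0.22 and, named after its value was seen, Gfi1b at -1.04 ± 0.25. The Gfi1b call was lost without the dox array A (adjusted p = 0.137) or B (0.145) or the no dox array B (0.0918). This list was called as lower (adjusted p = 0.00246; adjusted p = 0.476 with an estimated correlation), a call lost without the no dox array A (0.0823) or the dox array C (0.0633). Of 19 G2/M genes 6 fell and 0 rose, and 12 fell when adjusted over the list alone (camera adjusted p = 5.95e-05; adjusted p = 0.476 with an estimated correlation). The kinesin Kif11 fell by 0.48 on the log2 scale (adjusted p = 0.0244), a call lost without any 12 h array but the dox array C. Its adjusted p was 0.0633, 0.0865 and 0.0648 without the no dox array A, B or C, and 0.0899 and 0.109 without the dox array A or B. The falls of both lists were uneven over the letters: the median of dox minus no dox was -0.65 on A, -0.53 on B and -0.05 on C for the G2/M genes, and -0.71, -0.63 and -0.19 for the progenitor genes. The dox arrays A and B lay apart from C on the fourth component as well.

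With only the 12 h arrays the calls of Wnt2b (adjusted p = 0.305), Wnt2 (0.311), Bmp2 (0.12), Bmp7 (0.0517), Bmp4 (0.297), Gata2 (0.0517), Gfi1b (0.112) and Kif11 (0.0991) were lost. The deposited value table ended those of Wnt2b (0.0542), Wnt2 (0.101), Bmp7 (0.112) and Bmp4 (0.0568), marked spots missing that of Wnt2b (0.0628, at 0.415), median scaling those of Wnt2 (0.0904) and Bmp7 (0.0971), and no filter on dim probes those of Wnt2 (0.0524), Bmp7 (0.0673) and Bmp4 (0.0506). Cyclic loess (0.0502) and no background correction (0.0504) ended that of Bmp7, and leaving out the 4 h no dox arrays A and B and the 12 h dox array C that of Wnt2 (0.0764, at 0.593), while Wnt2b stood at 0.417 (0.0364). A dimmer second probe did not pass for Krt79 (0.63 ± 0.37, adjusted p = 0.37), Bmp2 (0.53 ± 0.19, 0.0986), Bmp7 (0.30 ± 0.21, 0.481), Kit (-0.01 ± 0.09, 0.978) or Kif11 (-0.12 ± 0.13, 0.683). With dox Lyl1 was above background on 2 of 3 arrays.

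Among the markers at 12 h, Tbx5, a cardiac transcription factor, rose by 0.50 ± 0.12 (adjusted p = 0.0196), a call lost without the dox array A (0.142) or the no dox array B (0.109), with median scaling (0.0729) or with only the 12 h arrays (0.152). Pecam1, an endothelial adhesion molecule, was lower by at least 1.41-fold (adjusted p = 0.000795). Isl1 stood at 0.98 ± 0.41 (adjusted p = 0.175) and Gata1 at -0.96 ± 0.31 (adjusted p = 0.0698). Both passed with the letters as a block (0.0467 and 0.00773), and Gata1 also with array weights (0.0085). Sfrp1, at 0.76 ± 0.29 (adjusted p = 0.136), passed with the block (0.0228) or array weights (0.034). The deposited value table gave Dtx1 at 2.883, Lyl1 at -1.798, Gpbar1 at 5.983 (fitted 3.596), Hes5 at 3.918 (fitted 2.396) and Pecam1 at -1.91 (fitted -0.696). In all 1249 probes passed, 486 higher and 763 lower with dox. This count leaned on every array of the comparison: it was 749, 366 and 365 without the no dox array A, B or C, 314 and 281 without the dox array A or B, and 4725 without the dox array C. With only the 12 h arrays in the fit 206 passed, of which 81.1% were higher with dox, against 38.9% of the 1249.

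At 24 h 6 of the 9 Notch targets rose, 0 fell and 3 did not pass, and 7 rose when adjusted over the list alone. Heyl rose by 3.61 ± 0.18 (adjusted p = 2.28e-12), Hey1 by 3.47 ± 0.36 (adjusted p = 3.13e-07), Hes5 at least 4.51-fold, and Hey2 by 0.91 ± 0.17. The list call held with an estimated correlation (adjusted p = 1.84e-13 and 0.00379). Its median of 1.76 was 2.707 with only probes above background on all arrays and 0.914 with marked spots missing, and the call held in both. The receptor Notch1 itself rose by 2.60 ± 0.27 and the ligand Dll4 by 1.10 ± 0.17, a call lost with the deposited value table (2.392, adjusted p = 0.2). The largest rises were Cpa1 (4.72 ± 0.25), Wnt4 (4.1 ± 0.46), Gpbar1 (4.05 ± 0.23), Bmp6 (3.99 ± 0.26), Wfikkn1 (3.84 ± 0.37) and Heyl. The largest falls were the homeobox gene Hlx (at least 18.5-fold), Hoxb1 (-3.69 ± 0.52), Cldn11 (at least 9.10-fold), Sertad4 (-3.30 ± 0.23) and the embryonic globins Hba-x (-3.06 ± 0.28) and Hbb-y (-2.94 ± 0.34). Without dox Dll4 and Gpbar1 were above background on 1 of 3 arrays and Cpa1 on 2.

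Among secreted signals at 24 h, Sfrp5 and Sfrp1, which bind and block Wnt proteins, rose at least 8.32-fold and by 2.14 ± 0.29, and the Wnt ligand Wnt2 by 2.53 ± 0.28. The 13 Wnt antagonists as a list were not called (adjusted p = 0.465), nor were the 16 Wnt ligands (adjusted p = 0.0653). Of 16 BMP and TGF-beta ligands 4 rose, 0 fell and 12 did not pass, with Bmp2 at 1.11 ± 0.18, Tgfb1 at 0.96 ± 0.18 and Bmp7 at 0.83 ± 0.21 beside Bmp6. Bmp7, named after its value was seen, was lost without any 24 h array but the no dox array B (adjusted p = 0.0765 and 0.0798 without the no dox array A or C, and 0.0841, 0.063 and 0.0556 without the dox array A, B or C). The list call (adjusted p = 0.0436; adjusted p = 0.131 with an estimated correlation) was lost without the no dox array A (0.0807) or C (0.0619) or the dox array A (0.0548) or C (0.0706). Of 17 cardiac transcription factors 3 rose (Tbx5 1.11 ± 0.12, Tbx20 1.30 ± 0.21, Isl1 1.98 ± 0.41), 13 did not pass and Hand1, named here after its value was seen, fell by 1.28 on the log2 scale (SE 0.27). That list was called (adjusted p = 0.0237; adjusted p = 0.151 with an estimated correlation), but not without the no dox array A (0.0807), and the 22 contractile genes were not (adjusted p = 0.83). The cell cycle inhibitor Cdkn1c was higher by at least 3.37-fold; it was the only called member of the 6 Cdk inhibitors (list adjusted p = 0.0186; adjusted p = 0.0876 with an estimated correlation; 0.0548 without the dox array A). Of 9 paraxial mesoderm and skeletal muscle genes Foxc2 (2.65 ± 0.41) and Twist1 (1.64 ± 0.28) rose and 7 did not pass (list adjusted p = 0.0436; adjusted p = 0.151 with an estimated correlation). This call was lost without the no dox array A (0.0807) or the dox array A (0.0599) or C (0.0706).

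Some blood genes fell at 24 h, and most called endothelial genes rose. Of 11 erythroid genes 3 fell, Hba-x, Hbb-y and the red cell regulator Klf1 (-0.77 ± 0.21), 0 rose and 8 did not pass. Adjusted over the list alone, 5 fell (camera adjusted p = 0.000114; adjusted p = 0.151 with an estimated correlation). The Klf1 call was lost without the no dox array A (0.232) or B (0.0705) or the dox array B (0.086) or C (0.251). Of 17 progenitor genes 3 fell, Kit (-1.41 ± 0.16), Gata1 (-1.28 ± 0.31) and Runx1 (-0.49 ± 0.14), and 0 rose (list adjusted p = 0.0436; adjusted p = 0.622 with an estimated correlation). This list call was lost without the no dox array A (0.318) or the dox array B (0.0954) or C (0.153). The Gata1 call was lost without the same arrays (0.105, 0.0527 and 0.0912), and that of Runx1 without these (0.354, 0.148 and 0.145; its value was -0.281 without the no dox array A) or the dox array A (0.0522). Of 19 endothelial genes 5 rose, 1 fell and 13 did not pass (list adjusted p = 0.0104; adjusted p = 0.526 with an estimated correlation). The 5 were Esam (1.68 ± 0.23), Icam2 (0.93 ± 0.16), Plvap (1.09 ± 0.20) and, named after their values were seen, Sox18 (0.97 ± 0.18) and Etv2 (0.60 ± 0.16). The Etv2 call was lost without the no dox array A (0.17) or C (0.0924) or the dox array B (0.103) or C (0.16). Pecam1 was the gene that fell, by at least 1.13-fold (adjusted p = 0.0212), a call lost without the no dox array B (0.144) or C (0.0546) or the dox array B (0.137) or C (0.0634). With the deposited value table the calls of Klf1 (-1.538, adjusted p = 0.0911), Runx1 (0.0576) and Etv2 (0.992, adjusted p = 0.224) were lost, and with only the 24 h arrays those of Klf1 (0.0769) and Runx1 (0.141). That of Runx1 was also lost with no filter on dim probes (0.0556) or with marked spots missing (0.0642), that of Etv2 with median scaling (0.0512) and that of Pecam1 with no background correction (0.223). Other probes that did not pass were 1 of Bmp7 (0.45 ± 0.21, adjusted p = 0.351), 1 of Kit (0 ± 0.09, 0.999) and 2 of Plvap (0.03 ± 0.15, 0.985, and -0.11 ± 0.23, 0.948). Without dox Plvap was above background on 2 of 3 arrays, and with dox Klf1 on 2. In the deposited value table Icam2 stood at 1.626, Plvap at 1.799, Hes5 at 4.14 (fitted 2.334), Sfrp5 at 5.46 (fitted 3.272), Cldn11 at -5.681 (fitted -3.47) and Pecam1 at -1.536 (fitted -0.453).

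Some markers passed at 24 h only under other settings. Tnnt2 stood at -0.98 ± 0.45 (adjusted p = 0.325), with all 3 dox arrays below all 3 no dox arrays, and passed with only the 24 h arrays (0.000877) or array weights (0.0197). Bmp4 at -0.44 ± 0.19 (adjusted p = 0.285) passed with the same 2 (0.025 and 0.014), and Kdr at -0.46 ± 0.22 (adjusted p = 0.382) with array weights (0.0199). Wnt5a at 0.59 ± 0.17 (adjusted p = 0.0538) passed with array weights (0.000179), only the 24 h arrays (0.00434), the letters as a block (0.00944), marked spots missing (0.0439), only probes of 1 gene symbol (0.044), a variance prior with trend and robust settings (0.0499), or without the 4 h no dox arrays A and B and the 12 h dox array C (0.00948). Hes1 stood at least 1.11-fold higher (adjusted p = 0.327; 0.0497 with array weights), with dox above background on 2 of 3 arrays. In all 1094 probes passed at 24 h, 584 higher and 510 lower.

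At 48 h, a day after dox had been washed out, heart muscle genes rose. Of 22 cardiac contractile genes 18 rose, 0 fell and 4 did not pass. The muscle LIM protein Csrp3 rose by 4.78 ± 0.43, the slow troponin Tnni1 by 1.85 ± 0.17, the atrial light chain Myl4 by 4.13 ± 0.38, Tnnt2 by 2.88 ± 0.45 and Myl7 at least 9.83-fold. The list was called at adjusted p = 7.85e-16 (adjusted p = 0.0657 with an estimated correlation). Of 17 cardiac transcription factors 10 rose, 6 did not pass and Mef2c, named here after its value was seen, fell by 0.47 on the log2 scale (SE 0.12), a call lost without the dox array A (adjusted p = 0.051). Among the 10, Myocd, a coactivator of muscle genes, rose by 3.92 ± 0.32, Nkx2-5 by 3.46 ± 0.32, Tbx5 by 1.33 ± 0.12 and Isl1 by 4.23 ± 0.41, whereas Gata4 stood at -0.18 ± 0.36 (adjusted p = 0.826). This call held with an estimated correlation (adjusted p = 1.37e-07 and 0.00226). The 6 largest rises were the calcium channel gene Cacna1d (4.99 ± 0.25), Csrp3, Cdo1 (4.46 ± 0.22), Col13a1 (4.26 ± 0.33), Isl1 and Myl4. The largest falls were Tdo2 (-5.01 ± 0.46), the matrix proteins Postn (-4.59 ± 0.27) and Lum (-3.29 ± 0.31), Hlx (-4.01 ± 0.23), Lmx1a (-3.23 ± 0.26) and Gas6 (-3.17 ± 0.24). With dox Hlx and Lum were above background on 1 of 3 arrays and Tdo2 on 2, and without dox Cacna1d on 2. Lum stood at -5.271 with the deposited value table.

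BMP ligands and their targets rose at 48 h as well. Of 16 BMP and TGF-beta ligands 8 rose, 7 did not pass and Gdf3 fell by 0.40 on the log2 scale (SE 0.11), a call lost without the no dox array A (0.0829) or the dox array A (0.0762) or with the deposited value table (-0.738, adjusted p = 0.0549). Among the 8 were Bmp7 at 2.72 ± 0.21, Bmp2 at 2.19 ± 0.18 and Tgfb1 at 1.14 ± 0.18 (list adjusted p = 0.00108, and 0.0136 with an estimated correlation). Of 14 other settings 1 ended this list call (camera adjusted p = 0.0577). Of 7 BMP targets 6 rose and Msx1 fell by 1.29 on the log2 scale (SE 0.24). Among the 6 were Id3 at 1.59 ± 0.16, Id1 at 1.72 ± 0.25 and Msx2 at 1.15 ± 0.18 (adjusted p = 0.000202; adjusted p = 0.0657 with an estimated correlation). Bmp4 rose by 0.64 ± 0.19 (adjusted p = 0.018), a call lost without the no dox array A (0.093) or the dox array B (0.0822), with the deposited value table (0.0542) or with median scaling (0.0622). Sfrp5 rose by 3.79 ± 0.22 and Sfrp1 by 1.05 ± 0.29 (adjusted p = 0.0122), the latter not without the no dox array A (0.693, adjusted p = 0.13) or the dox array B (0.0788) or with only the 48 h arrays (0.0529). Among 9 Notch targets Hey1 (3.40 ± 0.36), Heyl (1.44 ± 0.18), Hey2 (1.13 ± 0.17) and Notch3 (at least 1.31-fold) still stood higher, Hes7 fell by 1.20 on the log2 scale (SE 0.12) and 4 did not pass. That list call (adjusted p = 0.0312; adjusted p = 0.44 with an estimated correlation) was lost without the dox array C (0.0673), and that of Notch3 without the same array (0.0707) or the no dox array B (0.0635). Hey2 stood at 1.702, Heyl at 2.318 and Notch3 at 1.988 (fitted 0.617) with the deposited value table. Gdf3, Msx1 and Notch3 were named here after their values were seen.

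Erythroid and matrix genes fell at 48 h. Of 11 erythroid genes 9 fell, 0 rose and 2 did not pass. Among the 9 were the anion exchanger Slc4a1 at -2.61 ± 0.26, Hemgn at -2.08 ± 0.21 and Hbb-y lower by at least 6.48-fold (list adjusted p = 1.37e-07; adjusted p = 0.0657 with an estimated correlation). Gata1, which drives red cell genes, fell by 1.39 on the log2 scale (SE 0.31, adjusted p = 0.00187), whereas Tal1 stood at -0.06 ± 0.13 (adjusted p = 0.853) and Runx1 at -0.22 ± 0.14 (adjusted p = 0.353). Of 18 matrix genes 10 fell, 2 rose and 6 did not pass, with the collagens Col1a2 at -2.48 ± 0.18 and Col5a2 at -2.39 ± 0.20 beside Postn (adjusted p = 0.00108; adjusted p = 0.43 with an estimated correlation). Those that rose were Vcan (2.17 ± 0.27) and Col4a1 (0.66 ± 0.17, lost without the dox array C at adjusted p = 0.0623). The median of the matrix list, -0.728, was -0.464 with marked spots missing (camera adjusted p = 0.0334). With only probes above background on all arrays it was -0.122, and the call was lost (0.279). Of 11 targets of ATF4, a regulator of amino acid stress genes, 7 fell, 3 did not pass and Vldlr rose by 1.11 ± 0.23. Among the 7 were Asns at -1.22 ± 0.15, Atf5 at -1.02 ± 0.13 and Mthfd2 at -1.06 ± 0.14 (adjusted p = 2.69e-05; adjusted p = 0.0753 with an estimated correlation). Of 19 endothelial genes 8 rose, 2 fell and 9 did not pass: Plvap rose by 1.50 ± 0.20 and Icam2 by 1.16 ± 0.16, the angiopoietin receptor Tek fell by 1.35 (SE 0.17) and Ets1 by 0.55 (SE 0.12) on the log2 scale. Vcan, Col4a1, Vldlr and Ets1 were named here after their values were seen. The endothelial call (adjusted p = 0.0474; adjusted p = 0.676 with an estimated correlation) was lost without the no dox array A (0.146) or the dox array A (0.191), or with the letters as a block (0.0691). Kdr stood at 0.59 ± 0.22 (adjusted p = 0.0711) and passed without the dox array B (0.0466) or the no dox array C (0.0344), or with marked spots missing (0.0401). Other probes that did not pass were 1 of Myocd (0.29 ± 0.12, adjusted p = 0.104) and 1 of the 3 of Plvap (-0.32 ± 0.23, 0.409). In all 4482 probes passed at 48 h, 2123 higher and 2359 lower.

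**Figure D2:**
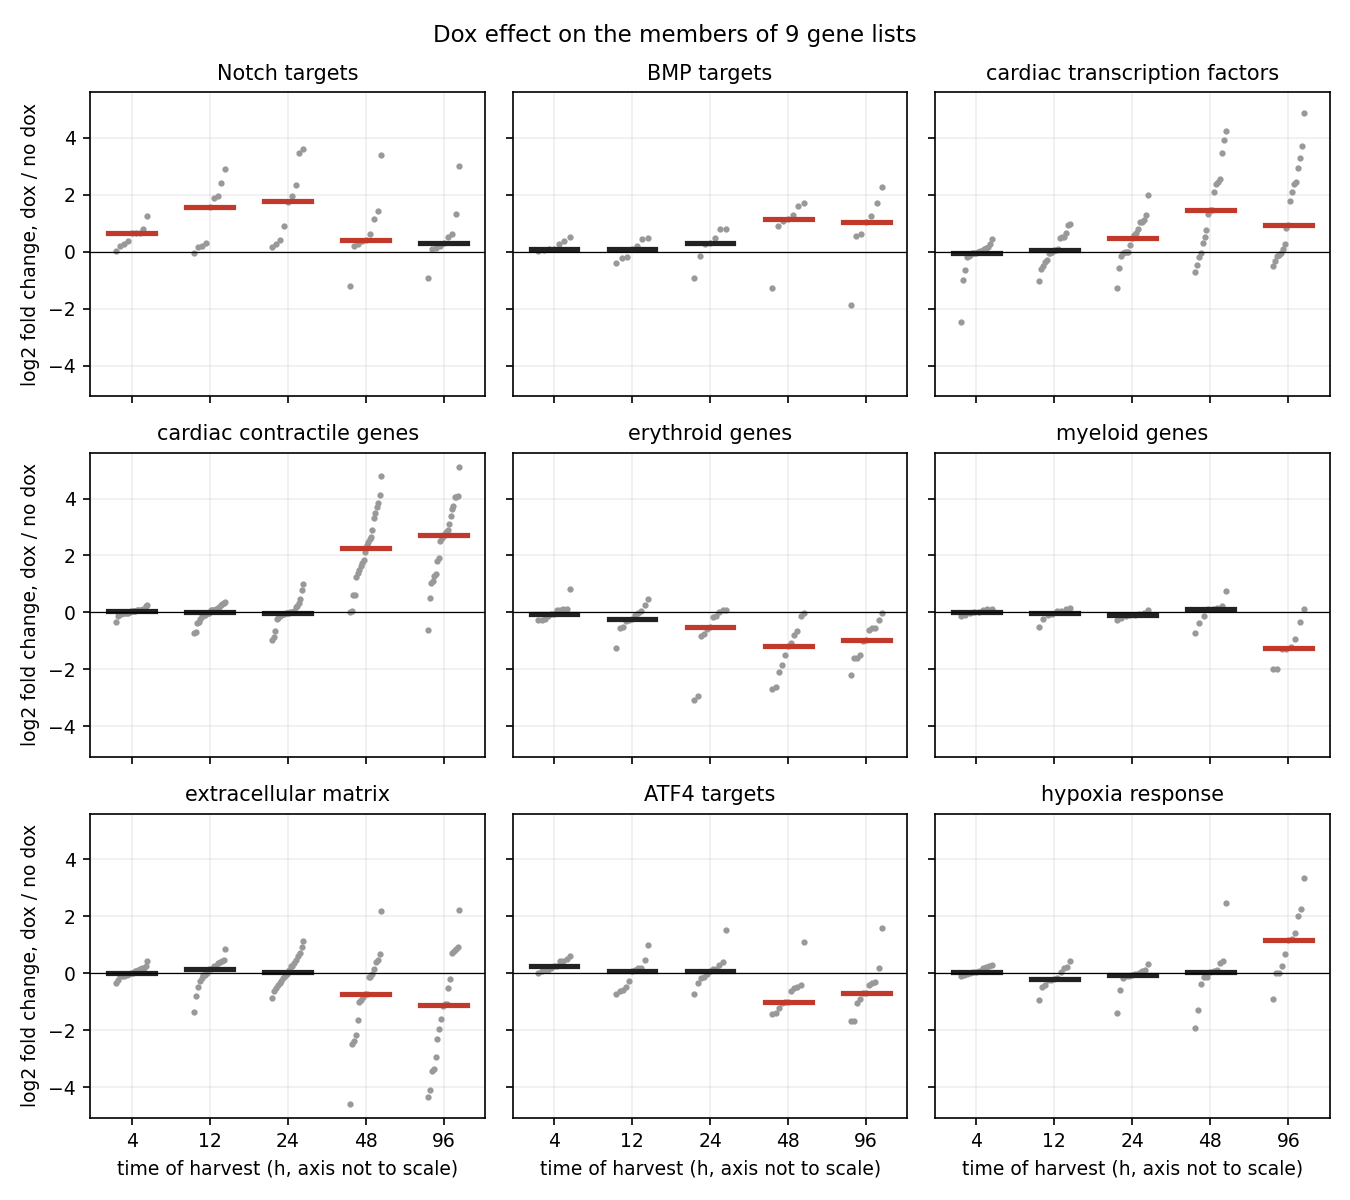
Log2 fold change of dox over no dox cells (vertical axis) for each measured member (grey points) of 9 gene lists against time of harvest in h (horizontal axis, not to scale). Bars mark the list's median, red where camera called the list at an adjusted p under 0.05 and black where it did not. The Notch targets had medians of 1.56 at 12 h and 1.76 at 24 h, and the cardiac contractile genes 2.25 at 48 h and 2.71 at 96 h.

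At 96 h heart muscle genes were again higher with dox. Of 22 contractile genes 20 rose, 0 fell and 2 did not pass, with the Z-disc genes Actn2 (3.63 ± 0.26) and Ldb3 (2.71 ± 0.20), the myosin heavy chain Myh7 (3.73 ± 0.31) and Tnnt2 (2.71 ± 0.45). The list was called at adjusted p = 3.44e-15 (adjusted p = 0.162 with an estimated correlation). Myl7, saturated with dox, was higher by at least 2.53-fold (adjusted p = 0.0363), a call lost without the no dox array A (0.291) or the dox array A (0.0622), B (0.0903) or C (0.0859). Its log2 fold change of 1.338 became 0.705 without the no dox array A, and the call was also lost with only the 96 h arrays (0.099) or no filter on dim probes (0.0502). Of 17 cardiac transcription factors 8 rose, 0 fell and 9 did not pass, and the 8 included Nkx2-5 (4.86 ± 0.32), Tbx5 (2.45 ± 0.12), Myocd (3.71 ± 0.32) and Isl1 (3.30 ± 0.41). Gata4 stood at -0.05 ± 0.36 (adjusted p = 0.949). This call held with an estimated correlation (adjusted p = 2.28e-05 and 0.0133). The 6 largest rises were the cardiac troponin Tnni3 (5.12 ± 0.47), the calcium-binding protein Pvalb (5.11 ± 0.17), Mlip (5.04 ± 0.17), Nkx2-5, Art3 (4.38 ± 0.19) and Tnnt1 (4.34 ± 0.14). The largest falls were Angptl7 (at least 25.3-fold), Pnoc (-4.58 ± 0.29), the matrix proteoglycans Dcn (-4.51 ± 0.36) and Lum (at least 19.1-fold), Gdf6 (-4.44 ± 0.29) and Postn (-4.36 ± 0.27). With dox Dcn was above background on 1 of 3 arrays and Gdf6 on 2, and without dox Actn2 on 1 and Myh7 and Nkx2-5 on 2. Dcn stood at -7.262 with the deposited value table.

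Erythroid and myeloid genes fell at 96 h. Of 11 erythroid genes 8 fell, 0 rose and 3 did not pass, with Slc4a1 at -2.19 ± 0.26 and Epb42 at -1.60 ± 0.26 (list adjusted p = 0.000572; adjusted p = 0.354 with an estimated correlation). Gata1, of the progenitor list, fell by 1.27 on the log2 scale (SE 0.31), a call lost with only the 96 h arrays (0.0659). Of 8 myeloid genes 6 fell, 0 rose and 2 did not pass. The lysozyme gene Lyz2 was lower by at least 2.02-fold, beside the receptor adaptors Tyrobp (-1.97 ± 0.33) and Fcer1g (-1.98 ± 0.34) (list adjusted p = 0.00224; adjusted p = 0.354 with an estimated correlation). Of 18 matrix genes 11 fell, 4 rose and 3 did not pass (list adjusted p = 0.000518; adjusted p = 0.354 with an estimated correlation). Col1a2 fell by 4.11 and Col5a2 by 3.36 on the log2 scale, while Vcan (2.23 ± 0.27), Lamb1 (0.84 ± 0.12), Col4a1 (0.70 ± 0.17) and Hapln1 (0.93 ± 0.31) rose. These 4 matrix genes that rose were named after their values were seen, and the Hapln1 call, whose arrays overlapped, was lost without the dox array A (0.624, adjusted p = 0.166) or C (0.952, adjusted p = 0.0548) or the no dox array B (0.515, adjusted p = 0.226), with only the 96 h arrays (0.175) or with the deposited value table (0.0588). Of 15 S-phase genes 8 fell and 0 rose, with Cdc6 at -1.70 ± 0.22, Mcm5 at -1.04 ± 0.18 and Mcm4 at -0.82 ± 0.16. The S-phase call (adjusted p = 0.0136; adjusted p = 0.582 with an estimated correlation) was lost without the dox array A (0.0581) or the no dox array B (0.0798).

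Genes of the response to low oxygen rose at 96 h: 7 of 11 were higher, 3 did not pass and Ndrg1 fell by 0.92 on the log2 scale. The peptide hormone Adm rose by 3.35 ± 0.45, Vegfa by 2.25 ± 0.35 and the glycolytic enzyme Pgk1 by 1.16 ± 0.19 (list adjusted p = 0.00463; adjusted p = 0.539 with an estimated correlation). Of 7 BMP targets 5 rose and Msx1 fell by 1.86 on the log2 scale. The 5 were Msx2 at 2.28 ± 0.18, Smad6 at 1.70 ± 0.24, Id3 at 1.04 ± 0.16, Id1 at 1.24 ± 0.25 and Bambi at 0.62 ± 0.18 (list adjusted p = 0.009; adjusted p = 0.354 with an estimated correlation). Ndrg1, Id3, Id1 and Bambi were named here after their values were seen. Of 11 ATF4 targets 6 fell, 1 rose and 4 did not pass, with Atf5 at -1.68 ± 0.13, Trib3 at -1.67 ± 0.20 and Vldlr at 1.59 ± 0.23 (list adjusted p = 0.0157; adjusted p = 0.47 with an estimated correlation). Among 9 Notch targets Hey1 (3.01 ± 0.36) and Heyl (1.31 ± 0.18) still stood higher, Hes7 fell by 0.92 and 6 did not pass, and the list was not called (adjusted p = 0.261; 0.0239 with only the arrays compared). Bmp4 rose by 1.23 ± 0.19 and Kdr by 0.80 ± 0.22, whereas Sfrp5 was lower by at least 1.64-fold. The 2 probes of Sfrp1 disagreed: the brighter over all arrays fell by 1.48 and the other rose by 1.44 ± 0.25 (adjusted p = 7.22e-05). Pecam1 stood at 0.30 ± 0.12 (adjusted p = 0.0536) and passed without the dox array B (0.0498) or the no dox array C (0.0127), with the letters as a block (0.0469), with marked spots missing (0.0446) or with only probes of 1 gene symbol (0.0496). Wnt5a stood at 0.34 ± 0.17 (adjusted p = 0.159) and passed without the no dox array B (0.533, adjusted p = 0.0284) or with array weights (0.0246); without dox it was above background on 1 of 3 arrays. With the deposited value table Sfrp5 stood at -2.013 (fitted -0.848), Lyz2 at -3.115 (fitted -1.277) and Hes1, at least 1.03-fold higher with dox (adjusted p = 0.252), at 1.348 (0.0224). With dox Hes1 was above background on 1 of 3 arrays. A second probe of Ndrg1 did not pass (-0.39 ± 0.26, adjusted p = 0.303). In all 7168 probes passed at 96 h, 3446 higher and 3722 lower.

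**Figure D3:**
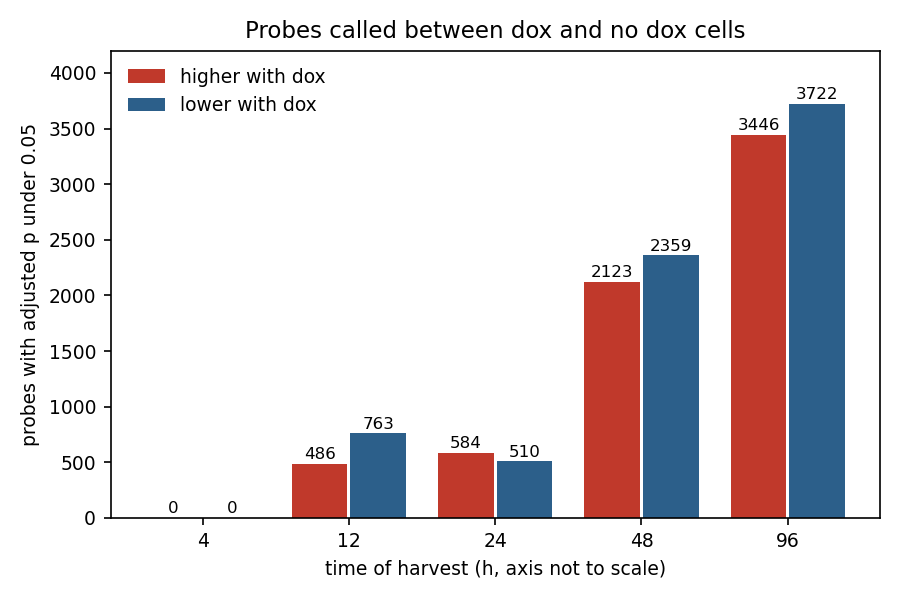
Number of probes with an adjusted p under 0.05 between dox and no dox cells (vertical axis) at each time of harvest in h (horizontal axis, not to scale), higher with dox in red and lower in blue. The counts were 0 at 4 h, 486 higher and 763 lower at 12 h, and 3446 higher and 3722 lower at 96 h.

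Taken over the 5 times, 8925 probes responded to dox at some time and 7427 had a dox effect that differed between times. Between 48 and 96 h, 1148 probes were called higher at both times, where 284 would be shared by chance, and 1371 were called lower at both, where 341 would be. Between 12 and 24 h, 196 were called higher at both (11 by chance) and 75 lower (15.1 by chance). Of the 763 probes called lower at 12 h, 91 were called lower at 48 h too (70.0 by chance) and 107 at 96 h (110 by chance), while 37 were called higher at 48 h and 75 at 96 h. Of the 486 called higher at 12 h, 159 were called higher at 48 h (40.1 by chance) and 133 at 96 h (65.1 by chance), while 38 were called lower at 48 h and 80 at 96 h. The dox effect itself changed between neighbouring times in 1689 probes from 4 to 12 h, 209 from 12 to 24 h, 1834 from 24 to 48 h and 2473 from 48 to 96 h. Of the 1689, 298 went up and 1391 down. In this step the 12 h dox arrays and the 4 h no dox arrays enter with the same sign. The 12 h dox arrays A and B and the 4 h no dox array A lay together on the fourth component, so a state they share would add up. None of these counts was rerun with an array left out. From 24 to 48 h the effect on the contractile genes increased by a median of 2.35 log2 units (camera adjusted p = 2.83e-18), and that on the Notch targets fell by 1.35 (adjusted p = 0.00169). Neither held with an estimated correlation (adjusted p = 0.0576 and 0.214). Of the 34 lists at 5 times, 32 list tests were called with the preset correlation and 6 with the estimated one. These 6 were Notch targets at 12 and 24 h, Wnt ligands at 12 h, BMP and TGF-beta ligands at 48 h, and cardiac transcription factors at 48 and 96 h. In 0 of the 32 did the list's median, mean and test differ in sign.

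The no dox cells give the course on which these effects sit, and here 96 h was compared with 4 h. Mesoderm and stem cell genes fell, with 9 of 10 primitive streak genes, including Mesp1 (-7.92 ± 0.28) and Mixl1 (-4.88 ± 0.30). So did 7 of 14 pluripotency genes, including Dppa5a (-6.06 ± 0.17) and Nanog (-4.46 ± 0.27), and 7 of 11 Wnt targets, including Sp5 (-5.24 ± 0.34) and Lef1 (-3.90 ± 0.19; a second Lef1 probe stood at -0.03 ± 0.15, adjusted p = 0.902). Genes of mature cells rose: 10 of 11 erythroid genes, with Hba-x higher by at least 393-fold and Hbb-y by at least 301-fold, and 14 of 19 endothelial genes, including Tek (2.59 ± 0.17). So did all 6 megakaryocyte genes and 6 of 8 myeloid genes, including Tyrobp (at least 9.29-fold). Contractile genes rose without dox too, in 16 of 22 members, including Tnni1 (5.53 ± 0.17) and Tnnt2 (5.02 ± 0.45). Rises were called for 6 of 10 smooth muscle genes, including Acta2 (5.38 ± 0.22), and 16 of 18 matrix genes, including Col3a1 (at least 296-fold). Nkx2-5 stood at 0.37 ± 0.32 (adjusted p = 0.383; without the 96 h no dox array A it stood at 0.897 and passed, adjusted p = 0.011), Isl1 fell by 2.46 and Kdr by 2.21 on the log2 scale. Mesp1, Mixl1 and Dppa5a were above background on 1 of 3 arrays at 96 h, and Nkx2-5 on 2 at both times. Hey1 fell without dox, from a mean log2 intensity of 9.96 at 4 h to 7.54 at 96 h (limma adjusted p = 4.99e-06). With dox its mean was 10.75 at 4 h and 10.55 at 96 h, so its dox effect goes with a fall in the no dox cells. Gata1 rose by 2.25 ± 0.31 without dox, and with dox its mean was 7.18 at 4 h and 8 at 96 h. The mean of Kdr with dox was 12.66 at 4 h and 11.42 at 96 h.

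Cell cycle genes fell over the same course, 15 of 19 G2/M and 13 of 15 S-phase genes, and 4 of 6 Cdk inhibitors rose: Cdkn2b (3.61 ± 0.32), Cdkn2c (1.01 ± 0.12), Cdkn1c (1.06 ± 0.26) and Cdkn1a (2.03 ± 0.56). Wnt ligands fell in 8 of 16 members, including Wnt3 (-2.15 ± 0.17), and BMP targets in 4 of 7. These were Msx2 (-2.55 ± 0.18), Id1 (-2.22 ± 0.25), Id3 (-1.31 ± 0.16) and Msx1 (-1.83 ± 0.24), while Bambi, above background on 2 of 3 arrays at 4 h, rose by 1.38 ± 0.18. Rises were also called for 5 of 8 endoderm genes, Rbp4 (1.62 ± 0.20), Foxa1 (0.75 ± 0.11), Trf (at least 1.29-fold), Ttr (0.56 ± 0.15) and Afp (0.32 ± 0.11). The Afp call was lost without the 4 h or the 96 h no dox array B (adjusted p = 0.0898 and 0.0994), with array weights (0.0521), with only the arrays compared (0.124) or without the 4 h no dox arrays A and B and the 12 h dox array C (0.0945), which also ended that of Cdkn1c (0.0599). This last fit leaves 1 array, C, at 4 h, which is assumed to vary like the other groups. Of 13 immediate early genes 8 rose, including Zfp36 (2.89 ± 0.14). Cdkn1a, Msx1, Bambi, Ttr and Afp were named here after their values were seen. Camera called all 17 lists of this paragraph and the one before it, with adjusted p between 3.97e-10 for the matrix genes and 0.0295 for the BMP targets, and 0 with the estimated correlation, where the lowest adjusted p was 0.0626. Of 14 other settings, 4 ended the call of the endoderm genes, 3 that of the BMP targets (1 of them the fit with 1 array at 4 h), 2 those of the smooth muscle, Cdk inhibitor and immediate early genes, and 1 those of the Wnt ligands, Wnt targets, erythroid, megakaryocyte and pluripotency genes. For the myeloid genes 1 of 13 did. The median of the smooth muscle genes, 2.197, was 0.365 with the deposited value table and 0.206 with marked spots missing. That table also gave Tyrobp 5.044 (fitted 3.352), Trf 3.259 (fitted 0.77), Ttr 0.991 and Afp 0.654. In all 11302 probes passed, 5679 higher and 5623 lower at 96 h.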

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

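The splits of the 4 h and 12 h arrays, the exchange of arrays, the low signal, the state shared with another array, the list medians by letter and the tests of the Notch4 probe were chosen only after the result was seen. What singled out the genes below is a dox effect that differed between the times of harvest, by limma's moderated F-test over the 5 times. Of 149 genes named for a dox effect, 136 differed in this way. Most of them were chosen for a rise or fall at a single time, which favours such a difference; over all probes it was called in 7427 of 25725. The number in brackets is the adjusted p of that test. The test does not say between which times the effect differed, and it was not rerun per gene with an array left out.

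Among the Notch targets and components these were Heyl (6.62e-09), Hey1 (0.000378), Hes5 (0.000343), Dtx1 (0.00673), Nrarp (0.0307), Hey2 (0.00785), Hes7 (2.21e-07), Notch1 (0.000163), Dll4 (0.00395) and Jag2 (0.000744). Wnt genes that differed were Wnt3 (0.0036), Wnt4 (2.01e-05), Wnt2 (4.28e-05), Wnt2b (7.86e-05), Sfrp5 (6.17e-11), Sfrp1 (6.19e-06), Dkk3 (1.78e-06), Lef1 (6.84e-07), Ccnd1 (0.0153), Myc (0.0213), Nkd1 (3.8e-06), Dkk2 (0.0109) and Cdx4 (0.0171). In the BMP and TGF-beta pathway they were Bmp6 (8.84e-07), Bmp2 (3.22e-05), Bmp4 (2.5e-05), Bmp7 (4.23e-06), Tgfb1 (0.000763), Id3 (0.000479), Id1 (0.018), Msx2 (1.84e-07), Msx1 (0.000649), Smad6 (0.000367) and Bambi (0.0394).

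Regulators of heart development made up another group, with Tbx5 (1.99e-09), Tbx20 (0.000424), Isl1 (1.73e-05), Nkx2-5 (8.34e-09) and Myocd (1.37e-07). The contractile and other heart muscle genes were Csrp3 (2.84e-07), Myl4 (6.39e-06), Myl7 (0.00293), Tnnt2 (4.49e-05), Tnni1 (8.07e-09), Tnni3 (6.91e-07), Actn2 (2.11e-07), Ldb3 (1.89e-07), Myh7 (3.56e-07), Tnnt1 (4.44e-13) and Cacna1d (2.07e-10). Smooth muscle genes with such a difference were Cnn1 (0.000694), Cald1 (0.000249), Actg2 (0.00719) and Synpo2 (4.46e-06), and in the mesoderm and skeletal muscle list they were Foxc2 (5.57e-05) and Twist1 (0.000111). For the blood genes the values were Kit (5.8e-06), Gata2 (0.000113), Lyl1 (0.000608), Gfi1b (0.00311), Gata1 (0.0339), Klf1 (0.0159), Hba-x (6.21e-06), Hbb-y (8.06e-05), Slc4a1 (1.75e-06), Hemgn (4.44e-05), Epb42 (0.000784), Vwf (6.66e-07), Ppbp (0.00416), Lyz2 (0.00175), Tyrobp (0.0011) and Fcer1g (0.00505). For the endothelial and arterial genes they were Pecam1 (0.000122), Kdr (0.00997), Esam (0.00187), Icam2 (0.000111), Plvap (0.00854), Tek (8.03e-08), Sox18 (3e-05), Ets1 (0.0079), Cldn5 (0.000858) and Nrp1 (0.00101).

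Matrix genes differed too, namely Postn (2.66e-10), Lum (1.11e-08), Dcn (4.31e-07), Col1a2 (3.31e-11), Col5a2 (1.34e-09), Vcan (4.4e-05), Lamb1 (0.000686), Hapln1 (0.0135) and Col13a1 (8.07e-08). Stress and oxygen response genes comprised Asns (3.91e-05), Atf5 (1.49e-07), Mthfd2 (2.51e-05), Trib3 (7.2e-05), Adm (0.000259), Vegfa (0.00136), Pgk1 (0.00184) and Ndrg1 (0.000124), immediate early genes Jun (2.23e-08), Atf3 (1.99e-05) and Ier2 (0.000124), and cell cycle genes Kif11 (0.0362), Cdc6 (7.36e-05), Mcm5 (0.0115), Mcm4 (0.0104) and Cdkn1c (0.00189). Stem cell, streak, endoderm and neural genes comprised Klf4 (1.45e-06), Esrrb (5.45e-06), Pou5f1 (0.0113), Eomes (0.00212), Ttr (1.64e-08) and Map2 (0.000536). Of the genes named for the size of their rise at a single time, the remaining ones were Gpbar1 (1.32e-11), Dmrta1 (5.41e-06), Krt79 (0.000124), Cdh1 (0.000141), Cpa1 (5.71e-09), Wfikkn1 (5e-06), Cdo1 (8.34e-11), Pvalb (4.44e-13), Mlip (4.95e-13) and Art3 (1.45e-11), and of those named for their fall Tdo2 (1.71e-05), Cldn11 (3.33e-09), Csrp1 (9.43e-05), Dusp9 (5.01e-05), Polg (1.71e-05), Hlx (1.91e-09), Hoxb1 (0.00472), Sertad4 (6.62e-06), Lmx1a (3.59e-07), Gas6 (1.25e-06), Angptl7 (6.93e-08), Pnoc (1.39e-08) and Gdf6 (3.29e-09).

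Gene lists also had dox effects that differed between neighbouring times, in 16 of 136 list tests (camera adjusted p in brackets). From 4 to 12 h the median effect increased by 0.69 for the Notch targets (0.0153) and fell by 0.61 for the haematopoietic progenitor genes (0.0292) and by 0.57 for the G2/M genes (6.39e-05). From 12 to 24 h it increased by 0.52 for the endothelial (0.0365), 0.38 for the G2/M (0.0119) and 0.51 for the S-phase genes (0.0119). From 24 to 48 h it increased by 2.35 for the contractile genes (2.83e-18), 0.58 for the cardiac transcription factors (3.54e-05) and 0.79 for the BMP targets (0.00169). Over the same step it fell by 1.35 for the Notch targets (0.00169), 0.58 for the erythroid (0.0119), 0.65 for the matrix (1.97e-05), 0.42 for the S-phase (0.00315) and 0.82 for the ATF4 genes (1.08e-06). From 48 to 96 h it fell by 1.16 for the myeloid genes (0.00234) and increased by 1.01 for the genes of low oxygen (0.000727). With an estimated correlation the cardiac transcription factors held (adjusted p = 0.0213) and the other lists did not (adjusted p from 0.0576 to 0.646). None of the 16 was rerun with an array left out, and those from 4 to 12 h use the arrays that lay together on the fourth component.

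At 12 h the dox array C stood apart from the dox arrays A and B. Each dox array was set against the mean of all 12 h no dox arrays. This shared baseline tends to raise every r between the dox arrays. Across genes, which are not independent replicates, r was 0.866 between the effects of A and B. Between either of these and C it was 0.269 and 0.349. With the dox effect at 24 h the effect of each array had r = 0.165 for A, 0.187 for B and 0.531 for C. The falls of the G2/M genes (median -0.65 on A, -0.53 on B and -0.05 on C) and of the progenitor genes (-0.71, -0.63 and -0.19) at 12 h may follow these arrays rather than dox. An exchange of the dox and no dox arrays C is argued against by the Notch targets, which were higher on dox C than on no dox C by a median of 2.26, and a low signal by its spots above background, 68.7% against at most 68.2% on the other arrays. A different point in the culture course stays open: dox A and B minus dox C had r = 0.522 with the change of the no dox cells from 12 to 24 h. This r was not set against other splits. For the dox effect at 96 h, other splits of the arrays reached an r of 0.427 in size with a change of the no dox cells. On the fourth component A and B, at -37.2 and -30.3, lay beyond the 24 h no dox arrays at -4.57 to -9.93. Whether a state was shared with the 4 h no dox array A cannot be told: the r = 0.381 between dox A and B minus dox C and the difference of no dox A from no dox C at 4 h restates the place of these arrays on the fourth component and adds no support. The design has no group that would part these.

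The count of 0 probes at 4 h, from limma with 2654 probes at an unadjusted p under 0.05, may owe something to the 4 h no dox array B. It had the lowest share of spots above background, 62.7%, and without it 36 probes passed, against at most 2 without any other array. This array was also the highest on the third component (64.7, next 29.3) and the lowest on the fifth (-59.1, next -22.2). Leaving it out therefore cannot tell its low signal from another difference of that sample. Whether the dox and no dox arrays B had been exchanged cannot be told: their Notch target median differed by -0.07, between the limits set for that test, beside 1.27 for the A arrays and 0.51 for the C arrays. A response that is still small at 4 h was not tested and stays open.

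The Notch4 probe was not called at any time in the main fit, though 7 of 18 alternatives called it at 12 h, 1 at 24 h and 2 at 48 h. A saturated signal is argued against, since the probe was saturated on 0 of the 30 arrays. A signal at background is argued against at 24 and 96 h, where the probe was above background on all 12 arrays, and cannot be told at 4, 12 and 48 h, where it was on 13 of 18. On those 12 arrays its log2 intensity was still low, 6.61 to 7.40, so a dim signal above background stays open. With only 1 Notch4 probe on the array it cannot be told whether the probe reads a part of the gene that the construct lacks, which could leave it blind to the transgene.

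Other splits of the arrays gave the following. Any dox effect, with 8925 probes, was matched by 1 of 100 splits within times, the real one, the highest other giving 5261. For the dox effect that differed between times, with 7427 probes, it was again 1 of 100 splits, with a highest other of 4280. No other split drawn gave as many, which makes a random grouping of the arrays an unlikely source of these counts. The splits treat the arrays of a time as exchangeable, and the labels do not say what the letters mark. For the comparisons of 3 with 3 arrays, the 10 splits are too few for a share under 0.05. At 4 h the real split gave 0 and the highest other 16; since any split gives as many as 0, as all 10 did, this comparison says nothing. At 12 h the real split gave 1249, and 2 of 10 splits gave as many: the other set the no dox array A and the dox arrays A and B against the rest and gave 1831, which points to a structure of the samples. The real split was the 1 with the highest count at 24 h (1094, highest other 0), 48 h (4482, highest other 0), 96 h (7168, highest other 513) and in the no dox course (11302, highest other 103).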

How the results depend on the processing

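The fits that used only probes with 1 gene symbol, that left out the 3 arrays that stand apart (4 h no dox A and B, 12 h dox C) or that left out the 4 h arrays were chosen after seeing the data, and the others before. Whether C or the pair A and B is the odd one among the 12 h dox arrays cannot be settled, since C is 1 array. A and B were alike (r = 0.866), yet several values set them apart rather than C. On the fourth component they lay at -37.2 and -30.3, and C at 24.2 among the 12 h no dox arrays. C was the nearest to the dox effect at 24 h (r = 0.531, against 0.165 for A and 0.187 for B). Its Notch target median was 2.26, against 1.17 for A and 1.24 for B. Leaving out C keeps the state of A and B, and no fit left out that pair. With the same probe per gene, no list or gene effect that passed the test in either fit changed direction under any alternative, but a second probe of Sfrp1, called too, ran the opposite way at 96 h. No background correction, median scaling, cyclic loess, no filter on dim probes, a variance prior with trend and robust settings, missing values for marked spots, probes with 1 gene symbol and leaving out the 4 h arrays kept every count they were run on within 1.5 times. Under the scaling alternatives the median effect over all probes was at most 0.086 log2 units (median scaling, 4 h). With only probes above background on all 30 arrays, fewer probes were tested, and 722 passed at 24 h in place of 1094 and 204 of the effects of named genes in place of 313. The deposited value table gave 622 probes at 12 h in place of 1249. Array weights gave 6067 at 12 h, 2745 at 24 h, 13597 for any dox effect and 12915 for an effect that differed between times. A fit on only the arrays compared gave 206 at 12 h, of which 81.1% were higher with dox against 38.9% of the 1249, 1720 at 24 h and 7329 for the no dox course in place of 11302. Without the 3 arrays that stand apart, 48 probes passed at 4 h and 5347 at 12 h; the 4 h no dox group is then array C alone, assumed to vary like the other groups, in every test that uses it. For these changes the cause was not tested. A threshold of at least 2-fold, which keeps fewer probes by its construction, left 349 at 12 h, 438 at 24 h, 1214 at 48 h, 1839 at 96 h and 3251 in the no dox course, and the estimated correlation left 6 of the 32 list calls. The letters A, B and C were also tried as a block, since the residual correlation of dox and no dox arrays of the same letter was above 0.1 in 10 of 15 pairs and the highest in 10, with both in 9 (range -0.0076 to 0.314). These pairs lie within a time, but the block is a letter effect common to all times, so a pairing within a time was not modelled. That block gave 1887 at 12 h, added 6 calls among the effects of named genes and left the other 510 on their side of the threshold. The 6 were Notch4 (adjusted p = 0.043), Gata1 (0.00773), Isl1 (0.0467) and Sfrp1 (0.0228) at 12 h, Wnt5a at 24 h (0.00944) and Pecam1 at 96 h (0.0469). It ended 2 list calls, the G2/M genes at 4 h (adjusted p = 0.0555) and the endothelial genes at 48 h (0.0691). Leaving out 1 array at a time gave 0 to 36 probes at 4 h, 281 to 4725 at 12 h, 810 to 852 at 24 h, 3295 to 4062 at 48 h, 5639 to 7033 at 96 h and 9658 to 10788 in the no dox course. In the same way it gave 7651 to 11157 for any dox effect, 6136 to 9798 for an effect that differed between times, 27 to 35 list calls and 293 to 317 effects of named genes. Among the effects of named genes, 82 lost and 6 gained a call in at least 1 of these fits, and 12 list tests lost theirs. Calls were also lost by 58 gene effects with only the arrays compared, 40 with the deposited value table and at most 15 under each other setting. Of 250 called dox effects of genes in the text, 32 were over 1.5 times larger with the deposited value table, and 1 with marked spots missing and 2 without the 3 arrays that stand apart were smaller by as much. These stand beside the results, and those of the 32 not printed there were Adm (3.726), Dll4 (1.495) and Lyz2 (-2.536) at 48 h and Hemgn (-1.528) and Lyl1 (-2.321) at 96 h. List tests, those of the no dox course included, lost 19 calls with marked spots missing, 18 with the deposited value table, 13 with only probes above background on all arrays, 9 without the 3 arrays that stand apart, 8 with array weights and at most 4 under each other setting, the estimated correlation (43 calls) and each array left out not counted. Of the 32 list calls for a dox effect, 20 ended under at least 1 of these 14 settings. These were endothelial genes at 48 h (9 settings), G2/M genes at 4 h (8), paraxial mesoderm and skeletal muscle genes (8), BMP and TGF-beta ligands (7), haematopoietic progenitor genes (5) and cardiac transcription factors (4) at 24 h, Wnt ligands at 12 h and S-phase genes at 96 h (3 each). Calls that ended under 2 settings were those of progenitor genes at 12 h, Cdk inhibitors at 24 h, Notch targets at 48 h, and BMP targets, ATF4 targets and genes of low oxygen at 96 h. Calls that ended under 1 were those of Notch targets at 4 h, erythroid genes at 24 h, BMP and TGF-beta ligands at 48 h, matrix genes at 48 and 96 h and myeloid genes at 96 h. A gene's call can rest on the probe used: among the called effects of genes named for a dox effect, other probes of the gene were called the same way 26 times, not called 22 times and called the opposite way 1 time. A block for slide or scan day was not run, since each array was its own slide and no scan day is given. Signal limits what dim genes can show: 62.7% to 68.7% of the spots of an array lay above background, and against a group at background a fold is given as a lower bound.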

Other observations

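Both hypotheses tested in this part were written before their results were seen, and no test of this part was chosen afterwards. Smooth muscle genes went both ways with dox, and their list was not called at any time (10 genes, lowest adjusted p = 0.1, at 48 h). At 48 h Synpo2 rose by 2.53 ± 0.20 and the actin-binding protein Cnn1 by 1.55 ± 0.31, while Cald1 fell by 1.57 on the log2 scale (SE 0.21). By 96 h Cnn1 stood at 2.43 ± 0.31, Cald1 at -1.32 ± 0.21 and the smooth muscle actin Actg2 at -2.79 ± 0.46. Single Wnt genes went both ways late, and none of the 4 Wnt lists was called at 48 or 96 h (lowest adjusted p = 0.449). Those that rose included the ligand Wnt2 by 3.13 ± 0.28 at 48 h and 3.08 ± 0.28 at 96 h, Lef1, a transcription factor of the pathway, by 1.97 ± 0.19 and 2.02 ± 0.19, and Dkk3 by 2.72 ± 0.29 at 96 h. The cyclin Ccnd1 rose by 0.66 ± 0.14 at 48 h. Among those that fell, the ligand Wnt2b stood at -0.91 ± 0.16 at 48 h and -0.61 ± 0.16 at 96 h, Nkd1 at -0.98 ± 0.23 at 48 h, Myc at -1.53 ± 0.30 and Cdx4 at -0.55 ± 0.12 (lost with only the 96 h arrays, adjusted p = 0.0548) at 96 h, when Dkk2 was lower by at least 1.47-fold. Ccnd1 was above background on 1 of 3 no dox arrays at 48 h and Myc on 1 of 3 dox arrays at 96 h. With the deposited value table Ccnd1 stood at 1.489, Wnt2b at -1.458 at 48 h, Myc at -2.91 and Dkk2 at -1.6 (fitted -0.655). Another probe did not pass for Synpo2 at 48 h (0.13 ± 0.10, adjusted p = 0.432) or for Lef1 at 48 h (-0.27 ± 0.15, 0.278) and 96 h (-0.19 ± 0.15, 0.408). A further Synpo2 probe did pass at 48 h (3.85 ± 0.24, adjusted p = 2.48e-11). Of the Notch pathway itself, Notch1 was still higher at 48 h (1.62 ± 0.27), and the ligand Jag2 rose by 2.25 ± 0.29 at 96 h (above background on 2 of 3 no dox arrays).

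Single vessel and platelet genes changed both ways at 96 h. Tek fell by 1.87 (SE 0.17), the tight junction gene Cldn5 by 1.39 (SE 0.20) and the receptor Nrp1 by 1.87 (SE 0.28) on the log2 scale, whereas Kdr rose, and the 19 endothelial genes were not called (adjusted p = 0.943). Vwf, a clotting protein of platelets and endothelium, rose by 1.94 ± 0.16, and the platelet chemokine Ppbp fell by 1.50 (SE 0.23; above background on 1 of 3 dox arrays; -3.239 with the deposited value table). Pluripotency genes also went both ways, with Klf4 at -2.16 ± 0.21, Esrrb at 0.94 ± 0.09 and Pou5f1 at 1.32 ± 0.23 at 96 h. Jun, an immediate early gene, rose by 1.36 ± 0.17 at 12 h and 1.41 ± 0.17 at 24 h and fell by 1.28 (SE 0.17) at 96 h, when Atf3 fell by 1.53 (SE 0.17) and Ier2 rose by 0.73 ± 0.15. The endoderm and blood plasma gene Ttr fell by 2.12 (SE 0.15) at 24 h, and at 48 h the streak gene Eomes fell by 2.07 (SE 0.31) and the neural gene Map2 by 2.02 (SE 0.27). A second probe of Eomes did not pass at 48 h (0.22 ± 0.27, adjusted p = 0.7).

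Of the 34 lists, 17 were not called for a dox effect at any time, at either correlation. Their lowest adjusted p with the preset correlation was 0.0555 at 12 h for the primitive streak and for the housekeeping genes, 0.0653 at 24 h for the immediate early genes, and 0.162 at 48 h for the arterial and for the epithelial-mesenchymal transition genes. It was 0.227 at 24 h for endoderm, 0.308 at 24 h for Notch components, 0.358 at 12 h for pluripotency, 0.384 at 24 h for megakaryocytes, 0.427 at 24 h for BMP antagonists, 0.449 at 96 h for Wnt antagonists and 0.456 at 24 h for venous genes. For Wnt receptors and p53 targets it was 0.639 at 48 h, and for Wnt targets and neural genes 0.731 at 12 h. In 51 of the list tests that were not called, the list's median, mean and test differed in sign.

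It was also asked whether the late dox effects run against the course of the no dox cells. Across genes, which are not independent replicates, the dox effect at 96 h had r = -0.328 with the change of the no dox cells from 12 to 48 h, and the 10 splits of the 96 h arrays reached 0.427 in size. The dox effect at 48 h had r = -0.207 with their change from 12 to 96 h, where the splits reached 0.239. Since other splits of the same arrays gave values as large, neither relation can be told from one that another grouping of these arrays gives.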
